A study of Mus musculus with 6 samples.

How the data were processed

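Total RNA was taken from a mouse embryonic stem cell line without Dicer, and biotinylated cRNA made from it was hybridised to Affymetrix arrays, per the labels. The 6 samples form 2 groups, 3 with a control siRNA and 3 with mimics of the miR-290 cluster, and their groups and replicate numbers come from the sample titles. All 6 carry 1 analysis date in the labels, so no batch could be separated from the others.

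The deposited values are linear intensities, 1 per probe set and array, for 45101 probe sets. The submitters' processing notes name GCRMA, whose output is usually on a log2 scale. The deposited intensities instead run from 0.057 to 46765, and on each array their mean without the lowest and highest 2% is 500, which is what the global scaling of the MAS 5.0 software gives. Which of these tools made the values is not settled by the sources used here. Background correction and detection calls of the arrays were not analysed here, so values near the floor cannot be told from background, and a fold change between low values is uncertain. Because the values are linear where log2 values had been assumed, they were log2-transformed with no offset. They were not normalized again for the main result. The ratio of 3′ to 5′ control probe sets lay between 1.27 and 1.43 for actin and between 0.794 and 0.813 for Gapdh, and no array stood apart.

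A gene was named only through the platform's annotation table. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed, which leaves them unnamed here. By gene identifier 34754 matched an annotation of the GRCm38.p6 assembly, and 0 symbols changed. The probe sets with 1 symbol covered 18194 genes. No genome build is named for the array, so no coordinates are given. For statements on genes, the probe set with the highest mean over the 6 arrays among those with 1 symbol stood for the gene, and disagreement with its other probe sets is stated.

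Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, 2-sided) on all 6 arrays without covariates. Control probe sets (64) were left out, and so were 15870 probe sets with a mean log2 intensity under 4, which left 29167 probe sets and 13815 genes. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Log2 fold changes are the mean of the mimic arrays minus the mean of the control arrays on the log2 scale; means and SDs are of linear intensities. Called probe sets without a single gene (33 of 376, 10 of them with several symbols) are counted and not named.

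The design, the filter, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named the 12 genes with the largest fall and the 8 with the largest rise among those past the threshold whose groups do not overlap; Dicer1, Rbl2, Dnmt3a, Dnmt3b, Dnmt3l, Cdkn1a, Lats2, Pou5f1, Nanog and Sox2 whatever their result; and for each list up to 4 members past the threshold with the largest change, or, where fewer than 2 passed, up to 2 members with the highest level. Members named beyond this rule because they passed over a list alone, or as single values, were chosen after their values were seen.

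The 21 lists held 352 genes, of which 307 were measured, 25 had no probe set with a single symbol and 20 were below the filter. They were reported targets of the miR-290 and miR-302 families, DNA methylation machinery, retinoblastoma and E2F genes, regulators of G1 to S phase, DNA replication and mitosis, pluripotency, epiblast and neural ectoderm, mesoderm, endoderm, trophectoderm, feeder fibroblasts, interferon response, small RNA pathway, p53 response and apoptosis, TGF-beta, Nodal and BMP signalling, epithelial and mesenchymal genes, Polycomb and histone repressors, germline genes silenced by DNA methylation, genes of the 2-cell stage, glycolysis and reference genes. Each list was tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the 21 lists, and its members were counted over all probe sets and adjusted over the list alone. The counts over a list alone were not corrected over the 21 lists. Of all tested probe sets, 20.1% had an unadjusted p under 0.05 in limma, so such members do not by themselves set a list apart. A planned test of 3′ UTR matches to the microRNA seeds was not run, because no 3′ UTR sequences were used here.

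The tests were first tested on simulated arrays built on the means and spreads of this comparison, with 50 of 29167 probe sets changed at each fold. The main test recovered 2% of 1.5-fold changes, 42% of 2-fold, 58% of 4-fold and 74% of 8-fold changes, with 9 false calls; with a prior that follows the signal level and robust estimation these were 24%, 44%, 56% and 78%, with 6 false calls. The simulation took each probe set's sample SD as its true spread. It also changed far fewer probe sets than the 20.1% with an unadjusted p under 0.05 in limma here, so the shares may differ in the real data. On simulated data for 13815 genes, drawn independently of one another, camera called a list of 20 genes shifted by −0.5 on the log2 scale. It called 0 of 20 unshifted lists. Correlated genes were not simulated, so false calls of lists whose genes move together were not checked.

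Alternatives were no filter and filters at a mean log2 of 6 and 8, the replicate number as a block, median centring, quantile normalization, the prior that follows the signal level with robust estimation, array weights, a floor at a log2 of 4, an offset of 16, a minimum fold of 1.5, an adjusted p under 0.01, 1 probe set per gene, the mean of a gene's probe sets, camera with an estimated correlation, limma's fry, and leaving out each array in turn.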

Results

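Gene expression was measured in a mouse embryonic stem cell line, 27H10, that lacks Dicer, the enzyme that releases mature microRNAs from their precursors. The cells were kept undifferentiated and were examined 24 h after transfection. In 3 samples the cells had received an siRNA against Renilla luciferase, a sequence with no intended target in mouse cells (control siRNA). In 3 further samples they had received synthetic mimics of the microRNAs of the miR-290 cluster, a group of microRNAs that embryonic stem cells with Dicer make in abundance. The comparison asks which transcripts change when these microRNAs are returned to cells that cannot make their own. Each sample was read on 1 Affymetrix array of 45101 probe sets, and the values are linear intensities. The median intensity per array lay between 41.7 and 44.9, and between 28.5% and 30.2% of the probe sets of an array were below 16. The arrays correlated at 0.963 to 0.969 within the groups and at 0.959 to 0.964 between them on the log2 scale. These values cover the tested probe sets, those with a mean log2 of at least 4, and leave out the dimmer ones. The number of arrays limits the precision of every value, and nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

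More transcripts were lower than higher in the cells that received the miR-290 mimics. Of 29167 probe sets tested, 276 were lower and 100 were higher than with the control siRNA at a Benjamini-Hochberg adjusted p under 0.05 in limma, so 73.4% of the changed probe sets were lower. Counted by gene from the same adjusted p-values, through the brightest probe set of each, these were 190 genes lower and 63 higher among 13815 genes. The changed probe sets differed by a median of 1.84-fold where they were lower and 1.89-fold where they were higher, and 96 of the lower and 43 of the higher ones differed by at least 2-fold. All 376 had 3 values in one group that lay beyond the 3 in the other, which their selection by p-value makes likely. Of all tested probe sets 29.2% did so, against 10% by chance. The first principal component of the brighter probe sets carried 60.1% of their variance and separated the groups. The smallest adjusted p was 0.0196, while 5848 probe sets (20.1%) had an unadjusted p under 0.05. The size of the set depended on the settings. With a prior variance that follows the signal level and robust estimation in 1 setting (the level-dependent robust prior) it was 1914 lower and 1379 higher, 349 of the 376 among them, with median centring of the arrays 103 lower and 50 higher, and with no filter on low values 0. Without 1 array at a time the same test called 0 probe sets, except for 1 higher without control replicate 3, with 4612 to 5205 at an unadjusted p under 0.05, whereas the level-dependent robust prior still called 1971 to 2844.

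**Figure D1:**
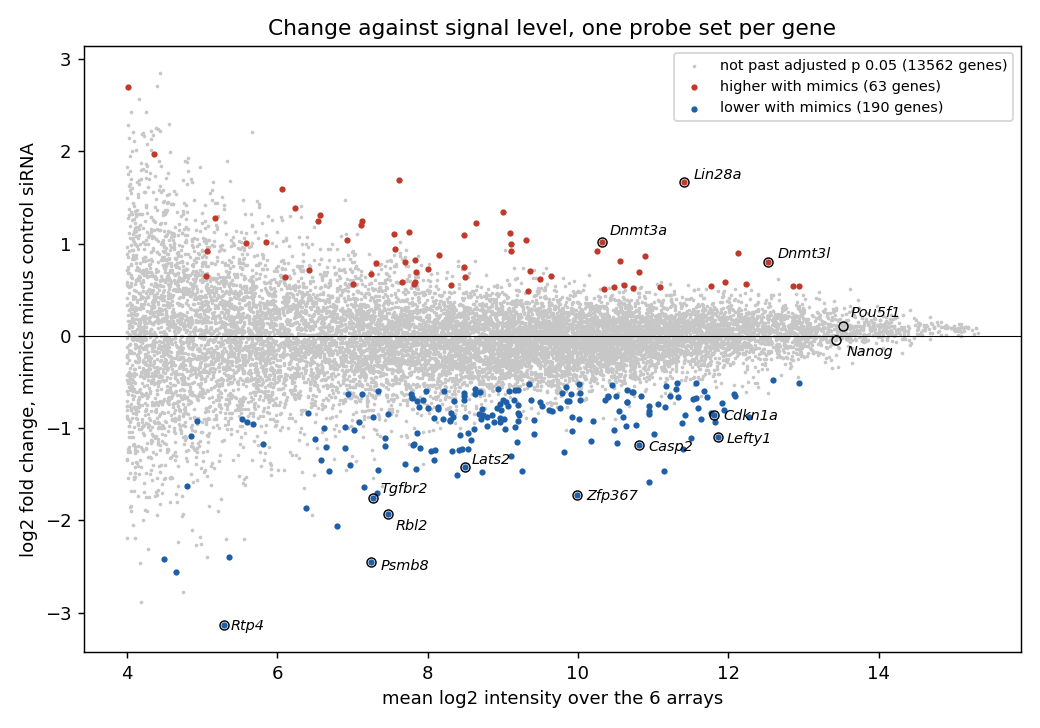
Log2 fold change (mimics minus control siRNA, vertical axis) against the mean log2 intensity over the 6 arrays (horizontal axis), with 1 point for each of 13815 genes; blue points are the 190 genes lower and red points the 63 genes higher at a limma adjusted p under 0.05. Among the labelled genes, Rbl2 lies at −1.93 and Lin28a at 1.67.

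The Dicer1 transcript itself gave intensities of 1129, 1177 and 1137 with the control siRNA and 1026, 1143 and 1090.4 with the mimics (limma adjusted p = 0.6). All 6 samples carry the deletion and the probe set may lie outside the deleted part, so this value checks nothing about the cells.

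Among the genes with the largest falls, Rtp4, which is induced by interferon, went from an intensity of 116 ± 14.3 with the control siRNA to 13.9 ± 5.03 with the mimics (SD, n = 3 each; log2 fold change −3.13 ± 0.30 SE, limma adjusted p = 0.034). Psmb8, a catalytic subunit of the immunoproteasome, fell by 2.45 on the log2 scale, and Gbp7, an interferon-inducible guanylate-binding protein, fell by 2.06. Rbl2, which encodes the retinoblastoma-like protein p130, fell from 350.3 ± 44.8 to 94.1 ± 26.7 (log2 fold change −1.93 ± 0.25 SE, limma adjusted p = 0.0453). Tgfbr2, the type II receptor for TGF-beta, fell from 286 ± 32.3 to 84.2 ± 4.35 (−1.76 ± 0.11 SE, limma adjusted p = 0.0231). The zinc finger gene Zfp367 fell 3.30-fold, from 1851 ± 117 to 560.3 ± 39.4 (limma adjusted p = 0.0196). The others were Tgfb1i1 (−2.56), Ms4a15 (−2.41), Grip2 (−2.39), the cytokine gene Il7 (−1.86), Zfp827 (−1.70) and the Wnt ligand gene Wnt9a (−1.64), and all 12 had limma adjusted p-values from 0.0196 to 0.0487. The mimic values of Rtp4, Tgfb1i1, Ms4a15 and Grip2 lay near the floor, where signal is not separated from background, so the size of these falls and their place among the largest are not settled: with an offset of 16 added to every value they were −2.15, −1.54, −1.41 and −1.68. Further probe sets of these genes gave log2 fold changes of −1.30 for Rbl2, −1.93 for Gbp7, −2.59 for Zfp827 and −0.34 for a dim Zfp367 probe set, but none of these 4 passed the test.

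The gene with the clearest rise was Lin28a, an RNA-binding protein that blocks the maturation of let-7 microRNAs. Its intensity went from 1536 ± 93.5 to 4869.5 ± 267 (SD, n = 3 each), a 3.17-fold rise (log2 fold change 1.67 ± 0.087 SE, limma adjusted p = 0.0196), and a second Lin28a probe set rose by 1.41. The other rises of the named set were in A630001G21Rik (2.69), Vrtn (1.97), Tmem150a (1.69), the trypsin inhibitor gene Spink1 (1.59), the synaptic gene Cplx1 (1.38), 2210409E12Rik (1.35) and Kdelr3 (1.31), which encodes a receptor that returns proteins to the endoplasmic reticulum, all on the log2 scale. A630001G21Rik and Vrtn had control intensities near the floor, 6.70 ± 2.59 and 10.7 ± 3.50, so their folds have no measured baseline, and with the offset of 16 they were 1.34 and 1.09. For Cplx1, 2 other probe sets of similar brightness gave −0.64 and −0.12 and did not pass the test, so its rise rests on 1 probe set. Of the 36 named genes that passed, 31 also passed with the level-dependent robust prior whichever array was left out; Tgfb1i1, Ms4a15, A630001G21Rik, Vrtn and Sox1 did not. Median centring ended 16 of the 36 calls, among them those of Rbl2, Lats2 and Dnmt3l.

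**Figure D2:**
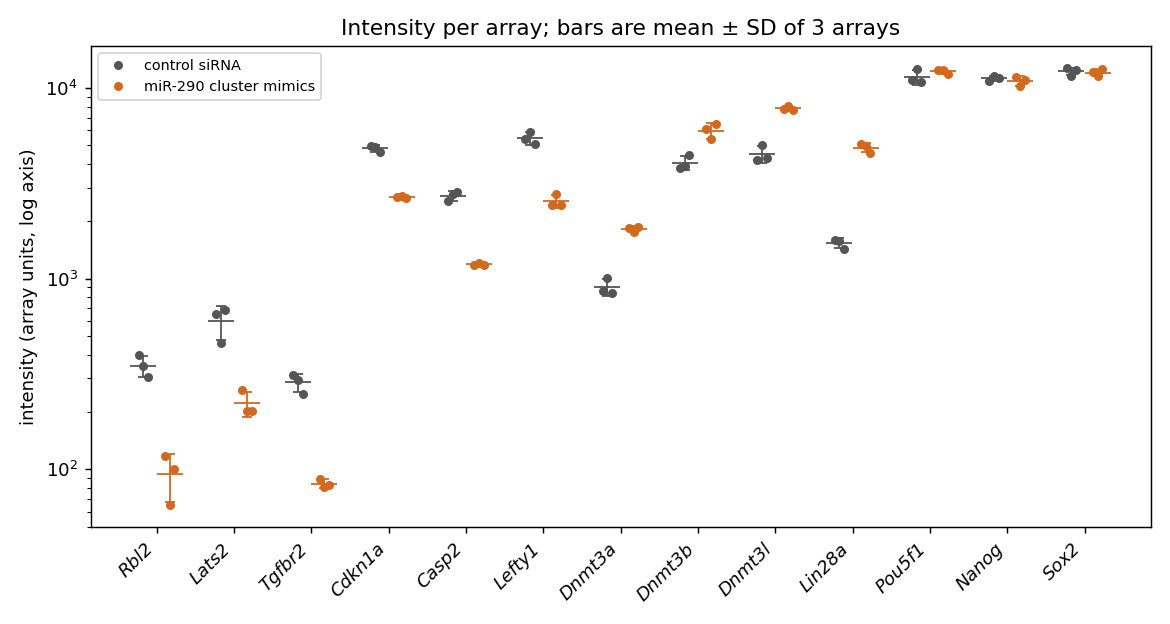
Intensity (array units, log axis) of 13 genes on each array; grey points are the 3 control siRNA arrays, orange points the 3 mimic arrays, and bars give the mean ± SD. For Rbl2, Lats2, Tgfbr2, Cdkn1a, Casp2 and Lefty1 every mimic value lies below every control value, for Dnmt3a, Dnmt3b, Dnmt3l and Lin28a every one lies above, and for Pou5f1, Nanog and Sox2 the groups overlap.

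Of 20 genes that earlier work reported as targets of the miR-290 and miR-302 families, 8 fell and 0 rose. The 8 were Rbl2, Tgfbr2, the Hippo pathway kinase gene Lats2, the Nodal antagonist genes Lefty2 and Lefty1, Casp2, the cell cycle inhibitor gene Cdkn1a and Mbd2. Cdkn1a went from 4839.6 ± 212 to 2678 ± 37.6 (SD, n = 3 each; log2 fold change −0.85 ± 0.071 SE), and Casp2 from 2718 ± 152 to 1193 ± 19.8 (−1.19 ± 0.076 SE), with limma adjusted p-values of 0.0287 and 0.0231. Lats2 fell by 1.42 (limma adjusted p = 0.0497), but its 5 probe sets disagreed: another one was called at −1.85, while 3 gave −0.47, −0.25 and 0.47 and did not pass. When p-values were adjusted over the list alone, 14 members were lower, among them Txnip (−0.53) and Rhoc (−0.63), and 1, the cyclin gene Ccnd1 (0.31), was higher. The median of the list was −0.58, and limma's camera, which compares a list with all other genes, gave an adjusted p of 6.33e-08 over the 21 lists. The call was lost when camera estimated the correlation between the genes (camera adjusted p = 0.0616). The correlation estimated for this list was −0.006, so the lost call is not evidence that its genes move together. Rbl2 was listed with knowledge of this study, so its direction is not independent evidence.

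Genes of the DNA methylation machinery moved in both directions. Of 17 measured, 2 rose and 1 fell. The de novo methyltransferase gene Dnmt3a went from 904 ± 90.2 to 1821 ± 63.8 (SD, n = 3 each; log2 fold change 1.01 ± 0.098 SE, limma adjusted p = 0.0338), and Dnmt3l, which encodes its catalytically inactive partner, from 4505 ± 444 to 7829 ± 238 (0.80 ± 0.096 SE, limma adjusted p = 0.0432). Mbd2, a methyl-CpG-binding protein gene, fell from 1185 ± 54.0 to 728 ± 48.5 (−0.70 ± 0.086 SE, limma adjusted p = 0.0433). The 5 Dnmt3a probe sets disagreed, with 1.01 and 1.06 called and 0.70, −0.09 and −0.35 not called. Dnmt3b, at 4047 ± 345 and 5977 ± 545, did not pass on its brighter probe set (0.56 ± 0.11 SE, limma adjusted p = 0.0778), whereas a dimmer one did (0.87, adjusted p = 0.0453). The level-dependent robust prior called the brighter one too (limma adjusted p = 0.000882), and called 6 members of the list higher and 1 lower. The maintenance methyltransferase gene Dnmt1 gave −0.19 and did not pass. The genes Dnmt3a, Dnmt3l, Dnmt3b and Mbd4 were higher and Mbd2 was lower, 4 and 1, when adjusted over the list alone. The list had a median of 0.13 and did not pass as a set (camera adjusted p = 0.0959). It was chosen with knowledge of this study, so its direction is not independent evidence.

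Among 18 genes of the retinoblastoma and E2F network, Rbl2 fell and 0 rose. The brightest other members, Mybl2 at 2420 ± 47.1 and 3190 ± 133 (SD, n = 3 each) and Tfdp1 at 2107 ± 34.1 and 2155 ± 99.0, did not pass (limma adjusted p = 0.0701 and 0.839), although a dimmer Mybl2 probe set rose by 0.99. The retinoblastoma gene Rb1 itself (−0.45), its relative Rbl1 (−0.32) and the E2F genes E2f2 (−1.10), E2f7 (−0.45) and E2f3 (−0.42) were among 6 lower members adjusted over the list alone, with Mybl2 as the 1 higher member. The median was −0.11 and the camera adjusted p was 0.256, so these members do not set the list apart from other genes. This list, too, was chosen with knowledge of this study.

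Of 21 regulators of the step from G1 to S phase, 3 fell and 0 rose. These were Lats2 and Cdkn1a, both also in the list of reported targets, and Lats1 (567 ± 56.9 to 258 ± 23.2, SD, n = 3 each, log2 fold change −1.13 ± 0.11 SE, limma adjusted p = 0.0365). A dimmer second Lats1 probe set gave −0.11 and did not pass. With p-values adjusted over the list alone, 4 were lower, the cyclin gene Ccne1 (−0.37) in addition, and 2 were higher, Myc (0.54) and Ccnd1 (0.31). The camera adjusted p was 0.244. Of 21 genes of DNA replication and mitosis 0 passed, also adjusted over the list alone, while the level-dependent robust prior called 3 higher (Mcm2, Rrm2 and Mcm5, by 0.28, 0.20 and 0.15) and 1 lower (Aurkb, −0.33). The list had a median of 0.03 and a camera adjusted p of 0.43. The replication clamp gene Pcna was at 22680 ± 1522 and 24953 ± 1038 (limma adjusted p = 0.424), and Cdc20 at 19011 ± 1671 and 18240 ± 646 (limma adjusted p = 0.778).

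Of 21 measured genes of TGF-beta, Nodal and BMP signalling, 3 fell (Tgfbr2, Lefty2 and Lefty1, all also in the list of reported targets) and 0 rose. Lefty1 went from 5452 ± 412 to 2547 ± 194 (SD, n = 3 each; log2 fold change −1.10 ± 0.099 SE, limma adjusted p = 0.0292) and Lefty2 from 1401 ± 163 to 585 ± 63.3 (−1.26 ± 0.13 SE, limma adjusted p = 0.0386). Adjusted over the list alone, 7 were lower, with Smad3 (−0.38), Smad1 (−0.36), Id1 (−0.30) and Bmpr2 (−0.43) added, and 3 were higher, Bmp4 (0.71), Nodal (0.34) and Id3 (0.23). The median was −0.19, and the list passed camera as lower (adjusted p = 0.0376). It lost the call at a camera adjusted p of 0.328 with an estimated correlation, which was −0.035 for this list. Over the camera alternatives its adjusted p lay between 0.0122 and 0.328. A different test, limma's fry, gave an adjusted p of 5.8e-05. The call also ended with quantile normalization (0.055), with filters at a mean log2 of 6 (0.0654) and 8 (0.112), with the mean of a gene's probe sets (0.0759), without control replicate 2 (0.0682), without mimic replicate 1 (0.0626) and without mimic replicate 3 (0.0609).

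Among the pluripotency genes, Lin28a alone passed over all probe sets: of 23 measured, 1 rose and 0 fell. The level-dependent robust prior called 5 higher, Lin28a, Dppa3, Tcl1 (0.44), Esrrb (0.23) and Utf1 (0.21), and 1 lower, Tfcp2l1 (−0.29). Pou5f1 was at 11430 ± 1029 and 12239 ± 386 (SD, n = 3 each; limma adjusted p = 0.586), Nanog at 11232 ± 327 and 10893 ± 615 (limma adjusted p = 0.784), and Sox2 at 12233 ± 539 and 12053 ± 538 (limma adjusted p = 0.904). The brightest members, Dppa5a and Zfp42, differed by 0.05 and 0.12 on the log2 scale and did not pass. Lin28a and Dppa3 (0.51) were the 2 higher members adjusted over the list alone, with 0 lower, and the camera adjusted p was 0.106.

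Few markers of differentiated lineages passed the test. In the epiblast and neural ectoderm list of 12, the neuronal tubulin gene Tubb3 rose from 584 ± 20.6 to 896 ± 65.6 (SD, n = 3 each; limma adjusted p = 0.0491) and the dim Sox1 fell from 71.6 ± 8.01 to 36.9 ± 3.98 (limma adjusted p = 0.0458); adjusted over the list alone, 2 were higher and 2 were lower. The median of this list was 0.04 and its mean −0.12, and camera gave an upward direction with an adjusted p of 0.756. In the trophectoderm list of 9, the simple-epithelium keratin genes Krt8 (1699.6 ± 99.1 to 1074.5 ± 64.9, limma adjusted p = 0.0457) and Krt18 (2070.2 ± 83.9 to 1362 ± 13.2, limma adjusted p = 0.0416) fell, as they did adjusted over the list alone, and the camera adjusted p was 0.149. Of 10 mesoderm genes 0 passed, with Bmp4 higher adjusted over the list alone and a camera adjusted p of 0.756. Bmp4 stood at 537 ± 72.4 and 873 ± 31.2, and Evx1 at 197 ± 51.1 and 123 ± 6.49. Of 14 endoderm genes 0 passed either way (camera adjusted p = 0.534), and Sparc, the brightest, was at 10233 ± 410 and 9963 ± 688.

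Genes of fibroblasts, which can serve as feeder cells for such cultures, included 1 that fell among 11, the actin-associated gene Tagln (539.5 ± 65.7 to 260.2 ± 21.3, SD, n = 3 each; limma adjusted p = 0.0422). Vim, at 11980 ± 335 and 9438 ± 266, did not pass on its brightest probe set (−0.34, limma adjusted p = 0.081), but 2 others fell by 0.52 and 0.48. Fn1 was at 3357 ± 64.7 and 4515 ± 26.0 (limma adjusted p = 0.0566). Vim and Fn1 are also in the epithelial and mesenchymal list. Of the fibroblast genes, 4 were lower (Tagln, S100a4, Dcn and Vim) and 2 were higher (Fn1 and Pdgfrb) adjusted over the list alone, and the camera adjusted p was 0.551. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 were below the filter, at no more than 24.4 on any control array.

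Of 15 genes of the type I interferon response, Irf9, a transcription factor of that response, fell from 337 ± 35.4 to 129 ± 7.51 (SD, n = 3 each; log2 fold change −1.38 ± 0.11 SE, limma adjusted p = 0.0277), and 0 rose. Adjusted over the list alone, 4 were lower: Irf9, Ifit1 (−1.33), Cxcl10 (−0.97) and Eif2ak2 (−0.41). The brightest members, Oas1a and Ddx58, gave −0.10 and 0.17 and did not pass. The list had a median of −0.13 and did not pass as a set (camera adjusted p = 0.106). In the small RNA pathway list of 15, Ago1, an Argonaute protein that carries microRNAs, fell from 3075 ± 124 to 2069 ± 79.8 (limma adjusted p = 0.0457). Drosha and Tnrc6a, the brightest members, did not pass. Adjusted over the list alone, 2 were lower (Ago1 and Mov10) and 1 was higher (Tarbp2), with a camera adjusted p of 0.43. Of 16 genes of the p53 response and apoptosis, Casp2 and Cdkn1a, both also in the list of reported targets, fell and 0 rose. Adjusted over the list alone 4 were lower, with Ei24 (−0.29), another listed target, and Perp (−0.27) added, and the camera adjusted p was 0.0905.

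In the remaining lists 0 genes passed over all probe sets. Of 17 epithelial and mesenchymal genes, 7 were lower adjusted over the list alone, among them Cldn7 (−0.67), Krt19 (−0.61), Cdh2 (−0.66) and Vim, and 2 were higher, Fn1 (0.43) and Epcam (0.25), with a camera adjusted p of 0.309. The epithelial cadherin gene Cdh1 was at 5389.7 ± 535 and 5468 ± 696 (SD, n = 3 each). Of 23 genes of Polycomb and other histone repressors, Rcor1 (−0.50), Bmi1 (−0.47) and Arid4b (−0.36) were lower and Cbx7 (0.36) was higher adjusted over the list alone (camera adjusted p = 0.756), while the brightest, Jarid2 and Mtf2, had limma adjusted p-values of 0.663 and 0.997. Of 13 germline genes that DNA methylation silences, 0 passed either way (camera adjusted p = 0.873), and Dppa3 and Tex19.1 gave 0.51 and 0.07. The 6 measured genes of the 2-cell stage all had positive log2 fold changes, with a median of 0.53, and just missed the threshold as a set (camera adjusted p = 0.0501). The threshold was passed without control replicate 1 (0.0297) and without control replicate 3 (0.0269), but not without any other single array. With an estimated correlation the camera adjusted p was 0.328. Usp17la was higher adjusted over the list alone (0.48), and the bright Eif1a gave 0.05. Of 14 glycolytic genes, Aldoa (0.41), Pkm (0.37) and Pgam1 (0.28) were higher adjusted over the list alone, while the glucose transporter genes Slc2a3 and Slc2a1 gave 0.14 and 0.08, and the camera adjusted p was 0.106. Of 11 reference genes 0 passed either way, with a median of 0.10 and a camera adjusted p of 0.271; Actb was at 26786 ± 1505 and 29633 ± 568, and Rpl13a at 36384 ± 2234 and 38575 ± 1396, which turned from 0.09 to −0.005 on the log2 scale after quantile normalization.

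**Figure D3:**
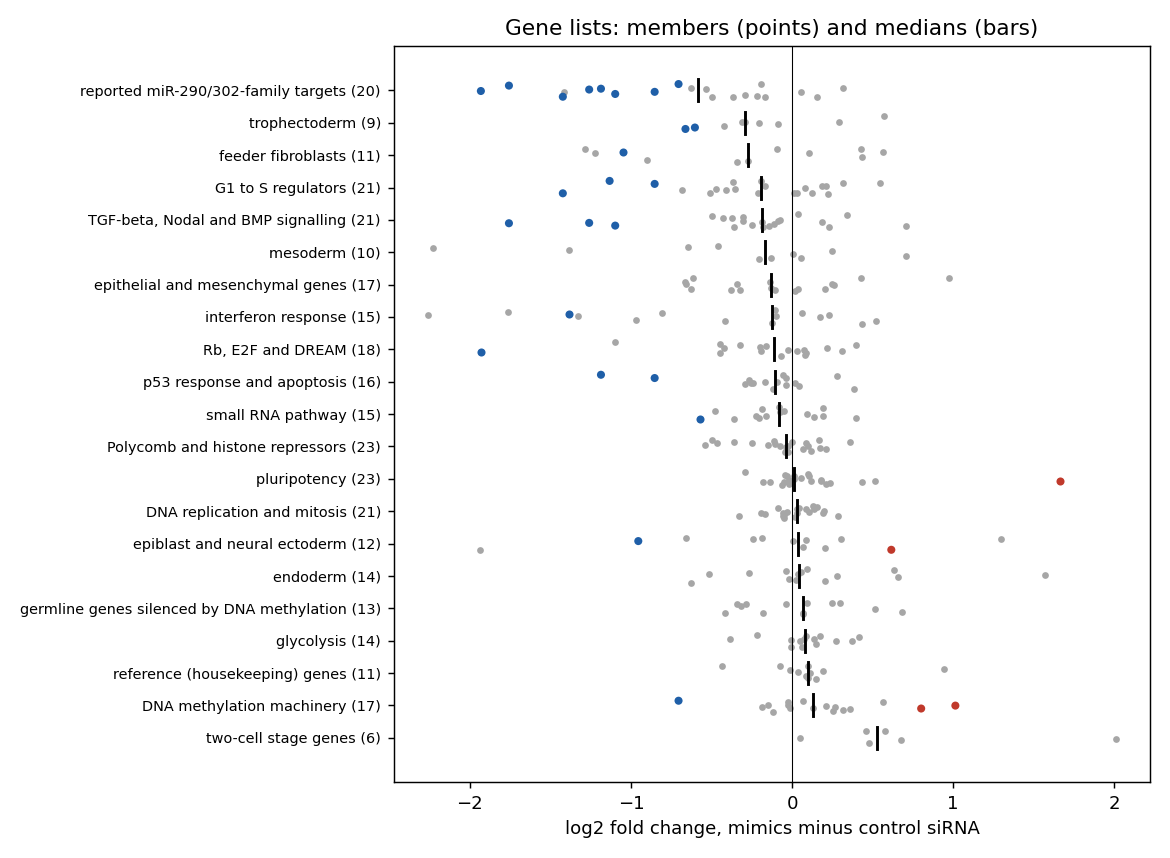
Log2 fold change (mimics minus control siRNA, horizontal axis) of the measured members of the 21 gene lists, ordered by median; points are genes, black bars are medians, numbers in brackets are members, and blue and red points are genes lower and higher at a limma adjusted p under 0.05. The list of reported targets has the lowest median, −0.58, and the 2-cell stage list the highest, 0.53.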

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

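The offset of 16, the filter at a mean log2 of 8, the replicate block with the level-dependent robust prior and the leaving out of arrays under that prior were chosen after the data were seen. Of the 6 arrays, 10 splits into 3 and 3 can be made, and 1 of them, the real one, gave as many changed probe sets; it gave 376 and the highest of the others gave 1, and 10 splits are too few for a share under 0.05. No called probe set changed sign under any alternative. The counts of 100 higher and 276 lower probe sets became 0 and 0 with no filter (5645 at an unadjusted p under 0.05 in limma), 851 and 1522 with a mean log2 of at least 6 (335 of 335 tested calls shared), 1200 and 1800 with at least 8, 50 and 103 with median centring, 1379 and 1914 with eBayes with trend and robust, 162 higher with the floor at a log2 of 4, 186 and 442 with an offset of 16, and 190 and 432 when the p-values of 1 probe set per gene were adjusted over these 13815 alone. Under an adjusted p of 0.01 they were 0 and 0, since the smallest adjusted p was 0.0196. Without 1 array at a time they ranged from 0 to 1 higher and from 0 to 0 lower, where 4612 to 5205 had an unadjusted p under 0.05 in limma. With trend and robust they were 932 and 1285, 1244 and 1600, 785 and 1186 without control replicates 1, 2 and 3, and 730 and 1296, 854 and 1417, 938 and 1516 without mimic replicates 1, 2 and 3, and 320 of the 376 calls were made every time. Array weights, quantile normalization and a minimum fold of 1.5 kept both counts within 1.5 times. The median replicate SD was 0.591 at a log2 of 4 to 6 and 0.129 at 8 to 10, and the prior carried 1.30 degrees of freedom over the probe sets above 4 and 3.49 above 8. Trend and robust estimation were not tried apart, and apart from the adjusted p of 0.01 the cause of the change in counts was not tested.

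Whether the replicate numbers pair the samples is not settled. Over all tested probe sets, residuals of arrays with the same number correlated at −0.0061, 0.012 and 0.024, and the 9 pairs ranged from −0.026 to 0.024. Dim, noisy probe sets weigh in these values. At a mean log2 of at least 8, the second principal component carried 15.3% of the variance. On it, control and mimic arrays stood at −0.211 and 0.0341 for replicate 1, 0.634 and 0.408 for replicate 2, and −0.356 and −0.51 for replicate 3. The replicate block gave 0 higher and 0 lower (5189 at an unadjusted p under 0.05 in limma), and the replicate block with trend and robust 1528 and 2030. The block with the constant prior moved the 2-cell stage list to an adjusted p of 0.0486 and changed no other list call.

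Among the lists, the reported targets had an adjusted p of 0.0616 with an estimated correlation. The TGF-beta, Nodal and BMP list had 0.0654 with a mean log2 of at least 6, 0.112 with at least 8, 0.055 with quantile normalization, 0.0759 with the mean of a gene's probe sets, 0.328 with an estimated correlation, and from 0.0269 to 0.0682 without 1 array at a time. With trend and robust, the adjusted p was 0.0309 for DNA methylation, p53 and 2-cell stage genes and 0.0386 for pluripotency and glycolysis. With no filter it was 0.0471 for p53 and 0.0322 for the 2-cell stage, which also gave 0.0452 with the offset of 16 and from 0.0269 to 0.0759 without 1 array at a time, the lowest without control replicate 3. Limma's fry, which asks whether a list's genes move one way on balance, gave 0.00584 for DNA methylation and for retinoblastoma and E2F genes, 0.000492 for G1 to S, 0.0233 for pluripotency, 0.0159 for trophectoderm, 0.000687 for interferon, 0.000298 for p53, 0.00172 for epithelial and mesenchymal genes, 0.0241 for the 2-cell stage and 0.0363 for glycolysis. The sign differed from the main value in 11 of all 398 list comparisons and in 35 of all 1605 comparisons of named genes, none of them for a list or gene that was called. Over the 68 named genes and their alternatives, 1185 comparisons kept their side of the threshold, 339 lost the call, mostly with no filter, with the block or without an array, and 81 gained it. Median centring ended 16 of the 36 calls, among them Rbl2 at an adjusted p of 0.0539, Lats2 and Dnmt3l. The planned seed-match test and its alternatives were not run.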

Other observations

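The tests of fibroblasts, of a type I interferon response and of scaling, and the 3 gene groups they concern, were chosen after the results were seen. Guanylate-binding, immunity-related GTPase and immunoproteasome genes, which interferon-gamma induces, were lower with the mimics: 6 of 19 fell and 0 rose in limma (Psmb8, Gbp7, Gbp2b, Gbp3, Gbp2 and Irgm1), 18 had a negative log2 fold change, and the median was −0.76, against −0.245 to 0.121 for the central 95% of 10000 random lists matched on level. The camera p was 2.37e-09, and 0.0109 with an estimated correlation, for a group picked from the same data. Gbp2b went from 571 ± 68.2 to 199 ± 3.47 and Irgm1 from 813 ± 15.5 to 429.5 ± 3.27 (SD, n = 3 each). Among other genes known to respond to interferon, also chosen after their values were seen, Xaf1 fell from 4111 ± 127 to 1759 ± 41.0, Zbp1 from 1017 ± 69.1 to 369 ± 29.5 and Ifi35 from 5028 ± 151 to 2628 ± 169 (limma adjusted p = 0.0196, 0.0231 and 0.0287). The interferon list fixed beforehand did not pass (camera adjusted p = 0.106, and 0.0519 to 0.934 over the camera alternatives, the highest with an upward direction at a mean log2 of at least 8), and its brightest members, Oas1a and Ddx58, gave −0.10 and 0.17. The kinase gene Jak2, which acts in interferon signalling, fell from 409 ± 25.6 to 173 ± 28.3.

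Outside the lists, and chosen after their values were seen, 3 annexin genes fell, Anxa1 (6744 ± 334 to 3656 ± 90.1), Anxa2 (4702 ± 513 to 2623 ± 39.3) and Anxa3 (2039.6 ± 182 to 1002 ± 45.8; SD, n = 3 each). The 9 measured annexin genes did not pass as a set (median −0.223, camera adjusted p = 0.137 over 223 groups of genes that share a symbol stem, 0.709 with an estimated correlation). The retinoic acid-binding protein genes Crabp1 (148 ± 23.0 to 321 ± 27.8) and Crabp2 (393 ± 27.1 to 786 ± 85.2) rose. Rpia, an enzyme gene of the pentose phosphate pathway, fell from 3772 ± 194 to 1363 ± 16.5. The 6 genes given with intensities passed limma with adjusted p-values from 0.0196 to 0.0444.

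For the lower guanylate-binding and immunoproteasome genes, fibroblast feeder cells in the control cultures are a candidate source that cannot be told apart from the other explanations. The 11 measured genes of the fibroblast list had a median of −0.276 (95% bootstrap interval −1.05 to 0.428, camera adjusted p = 0.551). Tagln fell, and, adjusted over the list alone, S100a4, Dcn and Vim were lower and Fn1 and Pdgfrb higher. The list's collagen genes Col1a1, Col1a2 and Col3a1 lay near the floor, at no more than 24.4 on any control array. Changes between such values decide nothing, but the control arrays gave no clear signal of these fibroblast genes. A type I interferon response to the control siRNA and a response to the mimics cannot be told apart, since no untransfected or mock-transfected arrays were used here: the 9 interferon list members with a mean log2 of at least 6 had a median of −0.413 (95% bootstrap interval −1.33 to 0.172), and 7 of the 9 had negative log2 fold changes. Direct repression of Jak2 or Irf9 by the mimics, a hypothesis, could also lower such genes and was not tested, because no 3′ UTR sequences were used.

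Transcripts that host small nucleolar RNAs had mostly positive changes with the mimics. In limma 3 of 15 rose (Snhg5, Snhg4 and Snhg16, by 0.86, 0.70 and 0.55), 14 were positive and the median was 0.468, against −0.168 to 0.134 for matched random lists (camera p = 4.02e-07, and 0.027 with an estimated correlation). The genes named Snhg were the first of the 223 stem groups, and adjusted over these the camera p was 0.000286. With an estimated correlation it was 0.679, so the call was lost, as it was for all of the 17 groups that had passed. That setting also raised the camera p of the reported targets, from 3.02e-09 to 0.00293, at an estimated correlation of −0.006. The lost calls alone therefore do not show that the genes of a group move together. Scaling that depends on brightness is a possible explanation, but after quantile normalization the median was 0.499 against −0.152 to 0.146 for matched lists. The matched lists hold genes drawn at random, so their range leaves out correlation between the hosts, estimated at 0.109. A response of these transcripts to the mimics stays open as a hypothesis, and no biological explanation was tested.

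The 76 mitochondrial ribosomal protein genes had mostly small positive changes, with 60 positive, 0 called in limma (22 with the level-dependent robust prior, 20 of them higher) and a median of 0.102, against −0.0222 to 0.073 for matched lists. After quantile normalization the median was 0.0767 against −0.049 to 0.0464. The matched lists hold genes drawn at random, whereas the correlation between these genes was estimated at 0.177. The range of the matched lists is therefore too narrow to decide whether brightness-dependent scaling is the cause. Among the stem groups, Mrpl kept its camera call after quantile normalization (adjusted p = 0.0452) and Mrps lost it (0.121). For the 76 genes the camera p was 4.14e-07 but 0.15 with an estimated correlation. Correlation between these genes may account for the set's p, but that setting also raised the camera p of the reported targets at an estimated correlation of −0.006. In a scan of 223 groups of genes that share a symbol stem, 17 passed camera, 0 with an estimated correlation and 6 after quantile normalization; the ribosomal protein genes named Rpl had a median of 0.094, which became 0.0096 after quantile normalization.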
